A study of Rattus norvegicus and Mus musculus with 18 samples.

How the data were processed

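Total RNA was measured by SMART-seq2, a method that copies polyadenylated RNA into full-length cDNA, amplifies it and fragments it by tagmentation, in 18 libraries of skin from adult mice and rats. The groups were 3 mouse wound dermis, 3 mouse wound epidermis, 3 rat wound dermis, 4 rat wound epidermis and 5 rat inter-follicular epidermis libraries. Wound tissue was taken 1 day after the scab fell off, and the inter-follicular epidermis, the skin surface between hair follicles, was lifted off by vacuum suction. Per the labels' protocols, reverse transcription began from 10 ng or 100 ng of RNA with 12 or 10 cycles of pre-amplification, and single-end reads were 86 or 43 bases long. Which library had which input or read length is not given in the sources used here, so neither could be used as a batch.

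The deposited values are TPM, the share of a library's transcripts that comes from each gene, which the authors computed for each library. Bowtie 1.0.0 and RSEM 1.2.31 are named with the builds mm10 and Rnor_6.0 per the submitters' processing notes. The gene annotation and the settings of these tools are not given in the sources used here. Each library summed to the same total within rounding. TPM keeps no record of how many reads were sequenced, so the depth of each library is unknown and no counting interval is given. TPM is a share of the library, so a few abundant genes that differ between tissues shift all the others. All columns matched a labelled sample.

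Mouse genes were listed by Ensembl identifier, and 49289 of 49548 were paired with a symbol, including 15946 of the 15982 tested. Rat genes were listed by Ensembl identifier too, and the files do not pair them with names; the tables used here paired 0 of 32457. The gene lists were therefore not tested in rat. The planned test of the difference between species and the planned count of genes present in only 1 species were not run, because genes could not be matched between the species. Rat results are given as counts, with at most 2 identifiers per direction. The tables were normalized separately, and no level was compared across species. Coordinates are 1-based mm10 positions from GENCODE, taken by Ensembl identifier.

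Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using the mean-variance trend. Genes with at least 1 TPM in at least 3 libraries of a species were kept, which left 15982 mouse and 15518 rat genes. The mouse fit held 6 libraries in 2 groups. Both rat comparisons came from one fit of 12 libraries in 3 groups. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and the number of genes that also changed by at least 1 on the log2 scale is given beside each count. A log2 fold change on this scale understates the change of genes near 1 TPM. Nothing in the labels says whether libraries of a group came from separate animals, so p-values measure the spread between these libraries.

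The 31 gene lists were fixed before the data were examined. The 28 with at least 4 tested mouse members were tested with camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. Melanocyte and skeletal muscle lists had 2 and 3 tested members, and mitochondrial transcripts were not analysed here. Named genes followed a rule fixed beforehand. Per direction it takes the 10 genes with the largest log2 fold change among those past the threshold, with a mean of at least 10 TPM in the higher group and no overlap between libraries, passing over clone and predicted names. It adds up to 4 members of each list with the smallest adjusted p, members needed to show that a list is mixed, and a fixed set of keratin, collagen and hair follicle signalling genes.

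The labels give groups the same replicate numbers. In rat wound epidermis and wound dermis, the deviations of same-numbered libraries from their group means correlated across genes at 0.15 to 0.22. Each of the 3 pairs correlated best with its own number. The numbers were therefore treated as possible pairs, though 3 pairs are weak evidence. The main rat counts, standard errors and p-values come from the fit without pairs. With the number as a block, 8096 genes were called in rat wound epidermis versus wound dermis, against 8756 without it. No count there changed by over 1.5 times. The block also joined inter-follicular libraries by number, where 0 of 4 correlated best with their own. It was therefore no clean test of the pairing.

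The per-gene test was tested on simulated data with 200 changed genes per comparison. These were drawn from the more abundant genes and were far fewer than the genes called in the real data. The recovered shares therefore do not carry over directly. For mouse wound epidermis versus wound dermis, over 15982 genes, it recovered 84% of genes changed by 2 on the log2 scale and 7% of those changed by 1, with 8 false calls. For rat wound epidermis versus wound dermis, over 15518 genes, it recovered 94% and 71%, with 7 false calls. For rat wound epidermis versus inter-follicular epidermis, over 15518 genes, it recovered 94% and 85%, with 7 false calls. The list test, over 15982 genes, found a simulated shift of 1 in 1 list and called 0 of the other lists. The simulated genes varied independently, while the estimated correlation within the real lists reached 0.90. This run therefore could not show how often lists of correlated genes are called wrongly. Alternatives were other pseudocounts, filters and scalings, no trend, the replicate block, and each library left out.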

Results

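Gene expression was measured in mouse and rat skin wounds 1 day after scab detachment, a time that the study's description gives as coinciding with hair follicle regeneration in mice, and in unwounded rat inter-follicular epidermis. Mouse wound epidermis held 13117 to 14012 genes at 1 TPM or more (n = 3), and mouse wound dermis held 15958 to 16257 (n = 3). Rat wound epidermis held 12466 to 13177 such genes (n = 4), rat wound dermis 14328 to 14485 (n = 3) and rat inter-follicular epidermis 12286 to 12530 (n = 5). The number of reads behind each library is unknown.

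The first comparison asked which genes separate mouse wound epidermis from the dermis beneath it. Genes of the cornified layer, the dead outer layer of the epidermis, were far higher in the epidermis. Lor, the main protein of the cornified envelope, stood at 3957 ± 1113 TPM in epidermis and 292 ± 483 TPM in dermis (SD, n = 3 each), a log2 fold change of 6.21 ± 1.55 (SE, limma adjusted p = 0.012). Wound dermis replicates 1, 2 and 3 decided its size, since without each in turn Lor stood at 4.95, 8.23 and 5.46. Col1a1, a chain of type I collagen, stood at 31900 ± 7448 TPM in dermis and 26.1 ± 23.5 TPM in epidermis and fell by 10.65 on the log2 scale (adjusted p = 3.6e-05), and stood at -9.82 without wound epidermis replicate 2 and -11.37 without replicate 3. Of 15982 genes, 2721 were higher and 6275 lower in epidermis, and 6950 also changed by at least 1 on the log2 scale. In 66.0% of the genes the libraries of both groups did not overlap, where chance gives 10%.

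The 10 genes with the highest log2 fold changes under the naming rule were Spink7, Lce3c, Lor, Il1f6, Lce3e, Rptn, Hrnr, Crct1, Lce1c and Lce1a1, from 7.54 for Spink7 to 5.96 for Lce1a1. Without wound dermis replicate 2 they stood at 7.45 (Lce3e) to 9.50 (Spink7), and their lowest values, without wound dermis replicate 1 or 3, were 4.54 (Rptn) to 6.16 (Spink7). All 17 tested members of the list of differentiating keratinocytes and the cornified envelope rose, over all genes and adjusted over the list alone, with a median of 5.11 (camera adjusted p = 1.4e-08; adjusted p = 0.35 with an estimated correlation). Krt10, a keratin of the suprabasal layers, reached 23308 ± 11800 TPM in epidermis against 1910 ± 3017 TPM in dermis, and Krt1 14214 ± 4616 against 1314 ± 2053 TPM. Krt10 lies on chromosome 11 from 99385254 to 99389364, Krt1 on chromosome 15 from 101845426 to 101850794, and Lor on chromosome 3 from 92080271 to 92083142 (mm10, protein-coding). All 16 members of the lipid barrier list rose, over all genes and adjusted over the list alone (camera adjusted p = 1.3e-08; adjusted p = 0.35 with an estimated correlation). They included Smpd1 at 2.73, Hmgcs1 at 1.69 and Degs1 at 1.46. Wound dermis replicate 2 held the differentiation genes at a median of 20.0% of the epidermis mean, against 1.35% and 0.52% in replicates 1 and 3. Without wound dermis replicates 1, 2 and 3 in turn Krt10 rose by 4.68, 7.02 and 4.32 and Krt1 by 4.78, 6.90 and 4.02. Without wound dermis replicate 1 the adjusted p of Krt10 was 0.053 and that of Krt1 0.056, and Lce1c missed it without wound epidermis replicate 1 or 2 (0.059 and 0.055) or wound dermis replicate 1 or 3 (0.075 in both) and without the filter (0.054).

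**Figure D1:**
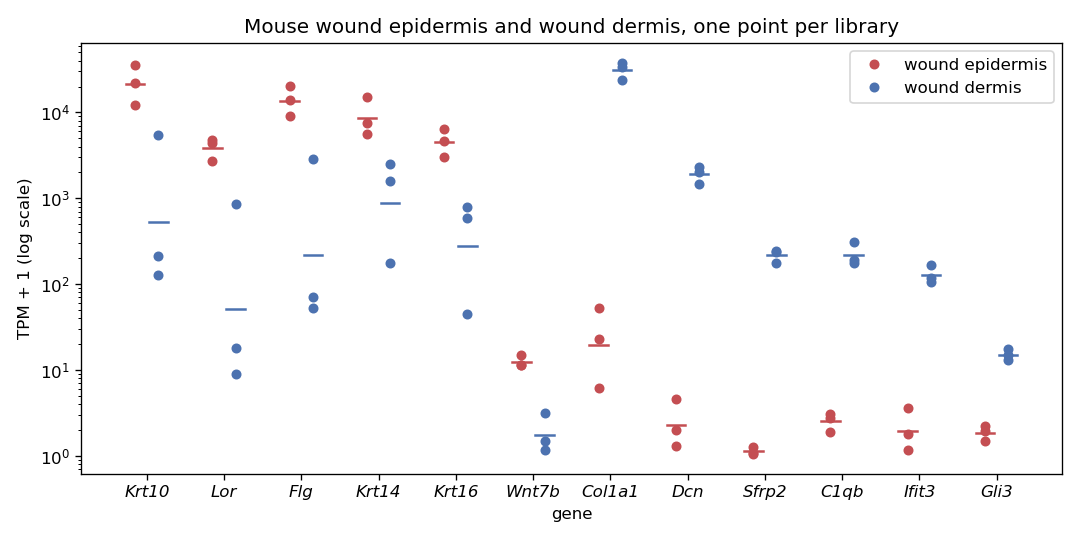
TPM + 1 on a log axis for 12 named genes in mouse wound epidermis and wound dermis, with 1 point per library and a line at the geometric mean of 3 libraries. Krt10 averaged 23308 TPM in epidermis and Col1a1 31900 TPM in dermis; the highest dermis point of Krt10, Lor and Flg is replicate 2.

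Of 8 tested basal keratinocyte genes 5 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.014; adjusted p = 0.46 with an estimated correlation; fry adjusted p = 0.14). Krt14 stood at 9349 ± 4967 TPM in epidermis and 1417 ± 1160 TPM in dermis (log2 fold change 3.27 ± 0.96, adjusted p = 0.023), Krt5 rose by 2.81, Krt15 by 4.44 and Trp63, the transcription factor of the basal layer, by 2.73. Itga6, Itgb4 and Dst, which anchor cells to the basement membrane, did not pass, at 0.195, 0.421 and -0.999; Itga6 passed under median-of-ratios scaling (0.65, adjusted p = 0.020) and Dst without wound epidermis replicate 1 (-1.39, adjusted p = 0.036). Without wound epidermis replicate 1 or 3 the adjusted p was 0.051 and 0.067 for Krt14, 0.064 and 0.076 for Krt5 and 0.072 and 0.057 for Krt15; without wound dermis replicate 1 it was 0.074 for Krt5 and 0.078 for Krt15, and without wound dermis replicate 3 it was 0.082 for Krt15. Without wound dermis replicate 2 the log2 fold changes were 4.01 for Krt14, 3.69 for Krt5, 6.07 for Krt15 and 3.48 for Trp63; without replicate 3 they were 2.10 for Krt14, 1.85 for Krt5 and 1.97 for Trp63, and without replicate 1 Krt15 stood at 3.26. Without the filter the adjusted p was 0.064 for Krt14, 0.066 for Krt5 and 0.060 for Krt15. The list had an adjusted p of 0.11 under quantile normalization.

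Of 18 tested wound-activated keratinocyte genes 11 rose and 3 fell, and adjusted over the list alone 13 rose and 3 fell (camera adjusted p = 0.0004; adjusted p = 0.35 with an estimated correlation). Krt16 rose by 4.01, Krt6a by 3.38, S100a9 by 2.66, Slpi by 2.57 and the growth factor Areg by 2.91. Itga5, a fibronectin receptor subunit, fell by 3.31, the urokinase receptor Plaur fell by 4.39 and the protease Mmp9 fell by 1.83. Without wound dermis replicate 3 Krt16 rose by 2.70 and Krt6a by 2.17, while Krt16 rose by 4.78 without replicate 2 and Krt6a by 4.01 without replicate 1. Krt6a missed the threshold without wound epidermis replicate 2 (adjusted p = 0.057) or replicate 3 (adjusted p = 0.061) and without the filter (adjusted p = 0.054).

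Dermal and vascular genes were lower in the epidermis. All 18 fibroblast and extracellular matrix genes fell, over all genes and adjusted over the list alone, with a median of -8.08 (camera adjusted p = 3.4e-09; adjusted p = 0.35 with an estimated correlation). The 10 lowest genes under the rule were Col1a1, Col3a1, Col1a2, Dpt, Lum, Dcn, Itm2a, Aspn, Rgs5 and Mfap4, from -10.65 to -8.77. Without wound epidermis replicate 2 Col1a2 stood at -9.59, Col3a1 at -9.50 and Rgs5 at -8.05, and without replicate 3 Col1a2 stood at -11.04 and Col3a1 at -11.03. Vim, the intermediate filament of mesenchymal cells, fell by 5.44. All 11 endothelial genes fell (camera adjusted p = 5.5e-06; adjusted p = 0.35 with an estimated correlation), as Cldn5 at -6.21 and Emcn at -5.46, and so did 8 of 9 myofibroblast and smooth muscle genes (camera adjusted p = 0.0016; adjusted p = 0.35 with an estimated correlation), as Myl9 at -7.22. Adjusted over the list alone these counts were 11 and 8. Col1a1 lies on chromosome 11 from 94936224 to 94953042 and Col3a1 on chromosome 1 from 45311538 to 45349706 (mm10, protein-coding).

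All 13 macrophage genes were lower in epidermis, over all genes and adjusted over the list alone (camera adjusted p = 7.4e-06; adjusted p = 0.35 with an estimated correlation), among them the complement genes C1qb at -6.42 and C1qc at -6.48. All 18 interferon response genes were lower, over all genes and adjusted over the list alone (camera adjusted p = 3.5e-05; adjusted p = 0.40 with an estimated correlation). They included Ifit3 at -6.02, Bst2 at -4.20, Irf7 at -4.01 and Tlr3, a sensor of double-stranded RNA, at -1.74. Of 10 tested inflammatory cytokine genes 4 were higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.31). The list's Il36a and Il36g were not found by symbol, so they were not tested. Il1f6, an older symbol of Il36a, was higher by 6.21 but was not counted in this list. Il18 was higher by 2.90 and Il1rn by 2.55, while Ccl2 fell by 5.80 and Il6 fell by 1.63; under quantile normalization Il6 stood at -1.06 (adjusted p = 0.0505). Of 14 immediate early and heat shock genes 9 rose and 1 fell, and adjusted over the list alone 10 rose and 1 fell (camera adjusted p = 2.3e-05; adjusted p = 0.35 with an estimated correlation). Hspa1a rose by 3.26, Hspb1 by 3.25 and Hspa1b by 2.95, while Nr4a1 fell by 1.93; without wound dermis replicate 2 Hspb1 rose by 3.95.

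Several signalling genes of hair follicle formation were near or below 1 TPM in both mouse tissues. Shh did not exceed 0.08 TPM in any of the 6 mouse libraries, Lhx2 0.08, Edar 0.12, Wnt7a 0.24, Fgf9 0.75, Msx2 0.98, Gli1 1.03 and Wnt10b 1.35 TPM, and none of them was tested. All 6 tested Hedgehog pathway genes fell, over all genes and adjusted over the list alone (camera adjusted p = 0.032; adjusted p = 0.40 with an estimated correlation), including Gli3 at -3.02, Gas1 at -2.73 and Ptch1 at -0.83; under quantile normalization Ptch1 stood at -0.04 (adjusted p = 0.87), and without wound epidermis replicate 2 Gas1 stood at -2.13. Of 13 Wnt ligand and target genes 3 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.46, and fry adjusted p = 0.0026, downward). Wnt7b rose by 2.82 (11.6 ± 2.0 against 0.95 ± 1.09 TPM), Wnt4 by 2.16 and Wnt3 by 2.53, while Wnt5a fell by 2.03, Nkd1 fell by 3.98 and Axin2 fell by 1.88. Lef1 did not pass at -0.33 (adjusted p = 0.27), and Wnt3 missed the threshold without wound epidermis replicate 1 or 3 (adjusted p = 0.070 and 0.062) or wound dermis replicate 1 or 3 (0.082 and 0.067) and without the filter (0.055). Wnt3 rose by 3.35 without wound dermis replicate 2 and by 1.88 without replicate 3. The Hedgehog list had an adjusted p of 0.061 without the filter, 0.086 with a filter of 5 TPM and 0.079 without the 50 most abundant genes.

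Of 17 Bmp and Tgf-beta genes 1 rose and 13 fell, and adjusted over the list alone 1 rose and 14 fell (camera adjusted p = 0.0089; adjusted p = 0.35 with an estimated correlation), with Tgfb3 at -4.45 and Inhba at -4.56; Bmp4 stood at -1.21 (adjusted p = 0.073, and 0.015 with the replicate block). Of 8 dermal papilla genes 7 fell and Prdm1 rose by 2.20, also adjusted over the list alone (camera adjusted p = 0.0087; adjusted p = 0.35 with an estimated correlation). Crabp1 stood at -6.83 and Vcan at -5.69. Of 9 hair follicle stem cell genes 1 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.11, and 0.48 with an estimated correlation; 0.049 and 0.048 without wound epidermis replicates 1 and 3, 0.019 without the filter, 0.044 with a filter of 5 TPM and 0.049 under median-of-ratios scaling), with Cd34 at -5.38, Tcf7l1 at -4.24 and Lgr5 at -3.70. Sox9 fell by 1.14 (adjusted p = 0.041) and missed the threshold without wound epidermis replicate 1 or 2 (adjusted p = 0.093 and 0.12) or wound dermis replicate 1 or 3 (0.062 and 0.11), without the filter (0.080), and under median-of-ratios scaling (0.12) or quantile normalization (0.15). Of 7 hair shaft and inner root sheath genes 5 rose, also adjusted over the list alone (camera adjusted p = 0.0058; adjusted p = 0.35 with an estimated correlation), among them Foxn1 by 2.04, Hoxc13 by 1.73 and Krt32 by 1.70; 12 of the list's 20 members lay below the filter, and without it the list had an adjusted p of 0.20. The dermal papilla list had an adjusted p of 0.068 with a filter of 5 TPM. In fry the hair follicle stem cell list passed, downward (fry adjusted p = 0.00056).

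Other scalings changed the balance of directions in this comparison. Of the called genes 30.2% were higher in epidermis, against 47.1% after median-of-ratios scaling and 52.8% after quantile normalization, and the median of all genes was -0.42, -0.04 and 0.08 in these fits. Without wound dermis replicate 1 the number of changed genes was 5427 and without replicate 3 it was 5288, against 8996 with all libraries; without replicate 2, which held epidermal transcripts, it was 6426. The filter left 13855, 13853 and 13823 genes in these fits, and with the 15982 tested genes held fixed the numbers were 7687, 7564 and 8594. With each library left out in turn and the filter applied anew, 3256 to 6406 genes were lower, against 6275. The fewest were lower without wound dermis replicate 3. The higher genes numbered 1943 to 2675, against 2721.

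The next comparison set rat wound epidermis against rat wound dermis. Of 15518 genes 3502 were higher and 5254 lower in epidermis, and 5155 also changed by at least 1 on the log2 scale. The files do not pair the rat identifiers with names. The gene ENSRNOG00000009602 stood at 5374 ± 1111 TPM in wound epidermis (n = 4) and 485 ± 466 TPM in wound dermis (n = 3), a log2 fold change of 5.57 ± 1.48 (SE, limma adjusted p = 0.0069), and ENSRNOG00000009383 rose by 5.16; without wound dermis replicate 3 they rose by 2.92 and 2.64, without replicate 1 by 6.68 and 6.06 and without replicate 2 by 7.11 and 6.77. ENSRNOG00000002382 stood at 0.33 ± 0.38 TPM in epidermis and 977 ± 95.5 TPM in dermis (log2 fold change -9.56 ± 0.18, adjusted p = 4.1e-11), and ENSRNOG00000045683 fell by 9.12. In 55.2% of the genes the libraries of both groups did not overlap. Chance gives 5.71% if the libraries are exchangeable, which ignores any pairing by number. The 5th percentile over 807 genes abundant in rat epidermis was 13.5% and 19.3% of the wound epidermis mean in wound dermis replicates 1 and 2, and 0.16% in replicate 3; without the first 2 libraries 6183 genes were called. Higher genes made up 40.0% of the called genes, and 54.0% after quantile normalization.

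**Figure D2:**
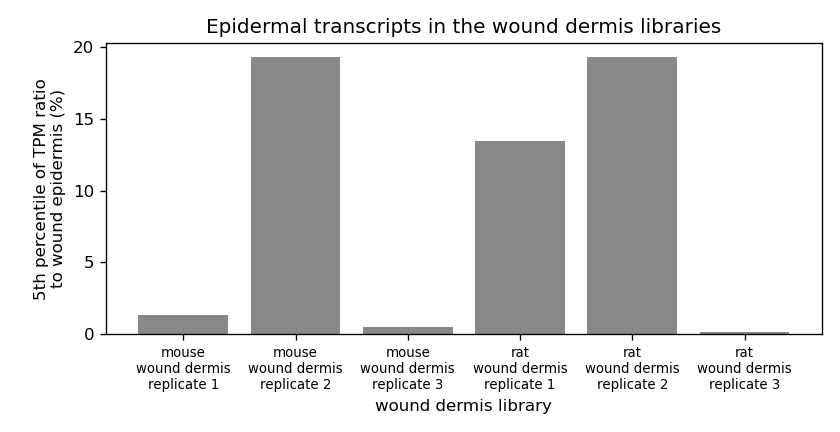
Bars give, for each wound dermis library, the 5th percentile over genes of the ratio of its TPM to the wound epidermis mean of the same species, in percent, from 0. The bar of mouse replicate 2 stands at 19.3%, those of rat replicates 1 and 2 at 13.5% and 19.3%, and the other 3 at 1.32%, 0.49% and 0.16%.

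The last comparison set rat wound epidermis against epidermis of unwounded rat skin. Of 15518 genes 5791 were higher and 3536 lower in wound epidermis, and 4908 also changed by at least 1 on the log2 scale. ENSRNOG00000007232 fell from 8393 ± 1950 TPM in inter-follicular epidermis (n = 5) to 0.47 ± 0.69 TPM in wound epidermis (n = 4), a log2 fold change of -12.54 ± 0.26 (SE, limma adjusted p = 3.3e-11), and ENSRNOG00000058083 from 9792 ± 4722 to 3.90 ± 1.30 TPM. ENSRNOG00000000579 stood at 1153 ± 272 TPM in wound epidermis and 5.70 ± 0.77 TPM in inter-follicular epidermis, and ENSRNOG00000037097 at 2199 ± 1553 and 12.9 ± 24.7 TPM, a log2 fold change of 8.55, or 9.43 without inter-follicular replicate 3. In 52.7% of the genes the libraries did not overlap, where chance gives 1.59%. Across genes, wound epidermis libraries correlated with inter-follicular libraries at 0.83 to 0.85 and with wound dermis replicates 1 and 2, which held epidermal transcripts, at 0.80 to 0.83 and with replicate 3 at 0.64 to 0.68; genes are not independent replicates.

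Over both rat comparisons, 1299 genes were higher and 837 lower in wound epidermis than in both other tissues. A further 2035 lay above inter-follicular epidermis and below dermis, and 1039 the other way round. Independent lists of these sizes would share 1307, 1197, 1961 and 798 genes, with 1299 and 2035 near that number, 837 below it and 1039 above it. Both comparisons used the same wound epidermis libraries, so their errors are linked and independent lists are no valid measure of chance overlap. Simulated unchanged groups shared 0. Almost no gene can be called in such groups, so this 0 was set in advance and is no measure of chance overlap. With the wound epidermis libraries divided between the comparisons, 6 ways, the counts were 916 to 1080, 536 to 637, 1393 to 2322 and 778 to 1033. Each comparison then rested on fewer wound epidermis libraries, so these counts are not directly comparable with the full ones. Higher genes made up 62.1% of the called genes in the comparison with inter-follicular epidermis, 49.9% after median-of-ratios scaling, 47.3% after quantile normalization and 50.5% without the 50 most abundant genes. Inter-follicular replicates 1 and 5 were closer to each other than any other pair of that group, with a median absolute deviation of the log2 ratio of 0.066 over 144 genes against 0.17 to 0.36 in the other 9 pairs; TPM cannot show whether this is within sampling noise, and with both averaged as 1 library 8837 genes were called against 9327.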

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

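The tests of RNA from another compartment in the dermis libraries were chosen after the values were seen, and the test of dermal RNA in rat wound epidermis was set out before its result. In rat inter-follicular epidermis replicate 3, ENSRNOG00000037097 stood at 57.1 TPM, against 0.64 to 2.49 TPM in the other 4 libraries. In rat wound epidermis replicate 4, ENSRNOG00000007232 stood at 1.5 TPM, against 0.07 to 0.18 TPM in the other 3. Both lay apart from their group by Dixon's test, which was run on 19 sets of values and flags about 1 in 20 by chance.

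Epidermal transcripts appeared in mouse wound dermis replicate 2 and in rat wound dermis replicates 1 and 2. A candidate explanation is wound epidermis mixed into these libraries at one share, which would put every abundant epidermal gene at or above that share. In mouse replicate 2 the 5th percentile over 1110 genes was 19.3% of the epidermis mean, close to the 20.0% median of the differentiation genes. These measures were also close in replicates 1 (1.32% and 1.35%) and 3 (0.49% and 0.52%), so their closeness decides nothing by itself. In replicate 2 the 17 differentiation genes ranged from 9.97% to 25.9%. The 13 basal and wound-activated genes under 5% in replicate 3 ranged from 7.26% to 87.6%. Since 19.3% is itself a 5th percentile, some genes lie below it by definition, so these ranges do not decide for or against one share. Over 119 rat genes that replicate 3 held under 1% of the wound epidermis mean, the median was 15.6% and 21.0% in replicates 1 and 2, and the 10th percentile was at least 0.58 of the median; the same ratio over 115 mouse genes was 0.18 in mouse replicate 1 and 0.60 in mouse replicate 2. Cells and free RNA were not told apart, and no biological explanation was tested.

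Mouse wound dermis replicate 1 held 13 basal and wound-activated keratinocyte genes at a median of 13.2% of the epidermis mean, as Krt17 at 29.2%, Krt6a at 21.4%, Krt14 at 17.2% and Krt15 at 0.59%. The 13 were chosen, from the 26 tested members of both lists, as those under 5% in replicate 3. Whole wound epidermis at one share was argued against, since the 17 differentiation genes had a median of 1.35% (Tgm3 at 18.1% and Dsc1 at 8.23% lay above it) and the 5th percentile over 1110 abundant genes was 1.32%. Hair follicle keratinocytes left in the dermis remain a candidate explanation that cannot be told apart, since the hair shaft and inner root sheath list had a median of 0.43 TPM, near the floor. That list covers the shaft and inner root sheath only, so it could not show keratinocytes of other parts of the follicle. No biological explanation was tested.

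In rat, 2035 genes lay above inter-follicular epidermis and below dermis in wound epidermis. Whole dermis carried into the wound epidermis libraries at one share was argued against as the whole cause. By the 5th percentile over 1315 genes that share was at most 0.55% to 2.89%. After it was subtracted 86.5% of the 2035 genes were still called higher, and their median log2 fold change went from 1.01 to 0.90. The same share was taken from every gene, so RNA of only some dermal cell types carried over was not tested and stays open. A difference between wounded and unwounded epidermis, which the design names, stays open, as does the way of collecting the tissue, since vacuum suction is given only for inter-follicular epidermis.

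For mouse wound epidermis versus wound dermis, 10 splits of the 6 libraries are too few for a share under 0.05; the real split called 8996 genes, as 1 of 10, and the highest other 0. For rat wound epidermis versus wound dermis, 1 of 35 splits called as many genes as the real 8756, the highest other calling 5209; only 8 splits part all 3 numbered pairs, which is too few for a share under 0.05, and among them the highest other called 3801. For rat wound epidermis versus inter-follicular epidermis, 100 of 126 possible splits were run, and only the real one called as many as 9327, the highest other calling 6058. This is 1 of 100, the smallest share these splits can give, which makes chance unlikely but does not exclude it. The share takes the libraries as independent, which the labels do not state.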

How the results depend on the processing

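The subtraction of shares, the fits with the tested genes held fixed, the averaging of inter-follicular replicates 1 and 5 and the joint removal of rat wound dermis replicates 1 and 2 were chosen after seeing the data. With each library left out in turn, mouse wound epidermis versus wound dermis called 5288 to 8546 genes, rat wound epidermis versus wound dermis 6453 to 8713, rat wound epidermis versus inter-follicular epidermis 8717 to 9108, and 12 to 16 mouse gene lists passed, of 23 to 26 that then had enough members. The mouse fits that moved by over 1.5 times were those without wound dermis replicate 1 (5427) and without wound dermis replicate 3 (5288); the filter left fewer genes in them, 13855 and 13853 against 15982, and 39.2% and 38.2% were called against 56.3%. With the tested genes held fixed, leaving out each library in turn gave 7415 to 8714 genes in this comparison, 7524 to 8737 in rat against dermis and 8742 to 9136 in rat against inter-follicular epidermis. Of 28 lists 15 passed in camera with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.35) and 22 in fry. Fry tests a list's own change from 0, so it also counts a shift shared by all genes, whose median was -0.42. With the epidermal share subtracted the counts were 9630 in mouse and 9407 in rat, without rat wound dermis replicates 1 and 2 the count was 6183, with the lone dermis library assumed to vary like the other groups, and with the dermal share subtracted it was 9079. In mouse the correlations of same-numbered libraries, from -0.14 to 0.19, were not all over 0.1, so the numbers were not taken as pairing, which leaves shared animals open, and 1 of 3 correlated best with its own number; the replicate block called 8404 genes and 15 lists. In rat the replicate block called 8096 genes against dermis and 8659 against inter-follicular epidermis, where correlations were -0.09 to 0.00 and 0 of 4 correlated best with their own number.

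Some values that did not pass the threshold changed sign. Lef1 stood at 0.46 and Mki67 at 0.29 under quantile normalization. Mbp stood at 0.048 under median-of-ratios scaling, 0.33 under quantile normalization and -1.01 to 0.32 with each library left out. Tnni2 stood at 0.34 and 0.70 under these scalings, -0.35 to 0.38 with each library left out and 0.035 with the epidermal share subtracted. Lists turned direction at these adjusted p-values: Fgf pathway 0.41 without the filter, 0.89 at 5 TPM, 0.99 under median-of-ratios scaling, 0.80 under quantile normalization and 0.0020 in fry; adipocytes 0.54 without the filter and 0.93 with the replicate block; Wnt ligands and targets 0.97 at 5 TPM and, with each library left out, 0.45 to 0.94, turning without wound dermis replicate 2; proliferation 0.026 to 0.98 with each library left out, turning without wound epidermis replicates 1 and 2; inflammatory cytokines 0.52 in fry. The median of all genes moved from -0.42 to -0.04 under median-of-ratios scaling and 0.08 under quantile normalization, so values near 0 can turn with it. Camera sets a list against the other genes, while fry tests its own change from 0. The Fgf list, with a median of -0.22, thus lay above the median of all genes and below 0. What turned the other values was not tested. The difference between species and the genes present in 1 species were not run, because genes could not be matched between the tables.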

Other observations

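The Reactome sets and the genes Actb, Xist, Ddx3y, Uty, Eif2s3y and Kdm5d were chosen after the values were seen. Among 658 Reactome sets, 59 were higher and 50 lower in mouse wound epidermis than in wound dermis with camera at the preset correlation, and 0 with an estimated correlation (adjusted p = 0.998 for cholesterol biosynthesis). Of 88 genes of translation elongation, mostly ribosomal proteins, 51 rose and 0 fell, with a median log2 fold change of 0.73. Of 22 cholesterol biosynthesis genes 18 rose and 1 fell, with a median of 1.97. Of 17 complement cascade genes 16 fell and 0 rose, with a median of -2.78.

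Most other fixed lists did not pass in mouse with camera at the preset correlation. The Notch, Fgf, Wnt inhibitor, Langerhans cell, Schwann cell and adipocyte lists passed in fry, downward (fry adjusted p = 0.0026, 0.0020, 0.00017, 0.017, 0.0049 and 0.00056). The placode, T cell, neutrophil and proliferation lists did not pass in fry (fry adjusted p = 0.35, 0.087, 0.22 and 0.35). Of 12 Notch pathway genes 5 fell and 0 rose (camera adjusted p = 0.47), as Hey1 at -2.73. Of 9 Fgf pathway genes 3 rose and 4 fell (camera adjusted p = 0.77), with Fgf22 higher by 4.44 (5.46 without wound dermis replicate 2) and Fgfr1 at -3.34; the camera direction was up while the median was -0.22. Of 6 Wnt inhibitors 4 fell, with a median of -2.68 (camera adjusted p = 0.062, 0.031 under median-of-ratios scaling, 0.023 under quantile normalization and 0.35 with an estimated correlation), as Sfrp2 at -7.58. Of 8 placode and ectodysplasin genes 2 rose and 2 fell (camera adjusted p = 0.26), with Traf6 at 2.50 and Trps1 at -1.53. Of 8 T cell genes 1 rose and 3 fell (camera adjusted p = 0.73), and adjusted over the list alone 0 rose and 3 fell. The 1 that rose, Cd5 (limma adjusted p = 0.049), missed the threshold with the replicate block (0.060), without the filter (0.11), with a pseudocount of 0.1 (0.064) and in 5 of the 6 fits that left out a library. Cd247, which fell, missed it in 4 of these 6 fits, without the filter (limma adjusted p = 0.051) and under quantile normalization (-0.21, limma adjusted p = 0.53). Of 7 Langerhans cell genes 5 fell (camera adjusted p = 0.42). Cd207 did not pass but was higher in each fit that left out a library (0.70 to 1.62). It passed under median-of-ratios scaling (1.58, limma adjusted p = 0.019), quantile normalization (1.84, 0.012) and without wound dermis replicate 2 (1.62, 0.022). Of 4 neutrophil genes 3 rose and 1 fell (camera adjusted p = 0.11). S100a8 and S100a9, which are also in the wound-activated keratinocyte list, rose with Cxcr2, while Csf3r fell by 3.10. The other members of the list lay below the filter. Of 4 Schwann cell genes 3 fell, with a median of -2.91 (camera adjusted p = 0.15, and 0.036 without the filter), and of 4 adipocyte genes 2 rose and 2 fell (0.92). Of 5 sebaceous gland genes 4 rose and 1 fell (camera adjusted p = 0.032; adjusted p = 0.35 with an estimated correlation), with Cidea at 3.57 and Soat1 at -3.61; without any 1 of the 3 wound dermis libraries its adjusted p was 0.067 to 0.078, and it also missed the threshold with a pseudocount of 5 (0.052), without the filter (0.14), with a filter of 5 TPM (0.11), under median-of-ratios scaling (0.12) or quantile normalization (0.14) and without the 50 most abundant genes (0.072). Of 19 proliferation genes 0 passed (camera adjusted p = 0.73); without wound epidermis replicate 3 the list had a camera adjusted p of 0.026 and Top2a stood at -1.49 (limma adjusted p = 0.019).

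Actb made up 10.9% to 15.6% of TPM in mouse wound dermis and 3.57% to 4.53% in wound epidermis. The Y-linked genes Ddx3y, Uty and Eif2s3y stood at 24.7 to 34.8 TPM in wound epidermis replicate 1 and 29.3 to 68.6 TPM in wound dermis replicate 1, and at or below 0.97 TPM in the other 4 mouse libraries. Kdm5d, also Y-linked, stood lower, at 4.32 and 2.67 TPM in the same libraries numbered 1 and at or below 0.79 TPM in the others. Xist stood at 0.04 and 0.01 TPM in both replicates numbered 1 and at 10.1 to 19.4 TPM in the others. By these genes both libraries numbered 1 came from males and the others from females, so each mouse group mixed sexes. In each tissue, replicate 1 thus came from other animals than the rest. Whether same-numbered libraries shared an animal stays open.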
